A study of Mus musculus with 4 samples.

How the data were processed

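Poly(A) RNA of sorted mouse SSCs was sequenced in 4 libraries, 2 of WT and 2 of Tex11PM/Y cells. Per the labels' protocols, the cells were grown in standard medium with regular passages, and libraries were made from 1 µg of RNA with a kit not stated to keep strand. Reads of a gene and of an antisense or overlapping partner therefore cannot be told apart. The submitters' processing notes name fastp, STAR, featureCounts, StringTie, DESeq2 and the mm10 build, with no roles or versions. The annotation release is not given in the sources used here.

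The authors deposited 3 tables. One holds whole-number read counts of 55335 genes, not normalized, in the layout of featureCounts per the file headers. The others hold FPKM values and TPM values of 37653 genes, per the file headers; these were made by the authors from their own alignments. Gene symbols came from the FPKM table for 37653 genes of the count table and from a reference name table for 17602, matched on the gene identifier; 80 had no symbol. Of the identifiers, 98.6% matched that table with their version number. Coordinates are those of the count table, in mm10. In each table both Tex11PM/Y columns carry the same name with the same replicate number. They are therefore called library A and library B, in the order of the columns, and cannot be tied to replicate numbers. WT columns are named by their replicate number. Every pair of libraries differed by more than sampling noise, with a chi-square over degrees of freedom from 21.1 to 247.

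Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM normalization, robust quasi-likelihood fits and F tests with genotype as the only term, and Benjamini-Hochberg adjustment over 17262 genes, with a threshold of 0.05. CPM values are scaled by TMM library sizes, and log2 CPM values used a prior count of 2. Lists of 850 gene entries, of which 849 were found, were tested with camera from limma 3.58.1, two-sided, with a preset correlation of 0.01 and adjustment over the 32 lists, with an estimated correlation and fry beside it. The 32 lists were SSC and undifferentiated spermatogonia, differentiating spermatogonia, meiotic prophase, crossover factors, spermatids, piRNA pathway, pluripotency, ERK response, p53 targets, recombination, cell cycle, glycolysis, oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis, interferon, integrated stress, heat shock, imprinted, fibroblast, Sertoli, Leydig, myoid, endothelial, macrophage, histone, ribosomal protein, X-linked germ cell, Y-linked, retinoic acid, BMP and Wnt lists. Calls per chromosome were compared with a two-sided Fisher exact test, and medians per chromosome were given bootstrap 95% intervals from 1000 resamples of genes, which cover the spread between genes only. No permutation test of 2 libraries against 2 can give a two-sided p under 0.333.

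Named genes followed a rule set before the data were examined, as were the design, the lists and most alternatives. The rule took Tex11; 11 fixed markers; genes past the threshold with the largest changes or, where fewer than 5 passed, the 5 smallest p in each direction; and up to 4 members of each list past the threshold. For the smallest p, groups had to be apart in CPM, the higher group needed a mean of at least 5 CPM, and predicted genes and pseudogenes were left out. Of the genes the rule took, 1 is not reported here, though it counts in the totals of comparisons. Pkd2l1 and members named inside the lists were chosen after their values were seen.

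The fit was tested on simulated data drawn for these libraries, with 200 changed genes, in 10 sets of 16726 to 16801 genes. With the dispersions estimated per gene, 1% of the 100 genes changed by 2-fold and 26.9% of the 100 changed by 4-fold were recovered. Each set gave on average 7.3 calls outside the 200 changed genes beside 27.9 true ones, or 20.7% of its calls. These can include chromosome 12 genes, which carried a 1.5-fold gain in WT replicate 2 in every set. The share is therefore not a false call rate over unchanged genes alone. With a dispersion of 0.01 instead, in 10 sets of 16948 to 16972 genes, 97.4% and 100% were recovered. A 1.5-fold gain of chromosome 12 in 1 library, a log2 value of 0.58, was recovered as 0.58.

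Alternatives were DESeq2 1.42.0, its size factors, library size alone, no count filter, a filter of at least 1 CPM in 2 libraries, a null of 0.5 log2 with glmTreat, limma on log2(FPKM + 1), log2(TPM + 1) and log2(FPKM + 0.1), and leaving out each library. The mean of the fibroblast list as a covariate and the unadjusted threshold for chromosomes were added after the data were seen.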

Results

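RNA was sequenced from cultured mouse spermatogonial stem cells (SSCs), the self-renewing germ cells of the testis, taken from mice of postnatal day 10 and collected on a cell sorter. The design compared wild-type (WT) cells with cells labelled Tex11PM/Y, after Tex11, an X-linked gene needed for crossover formation in meiosis. The labels do not define PM. Each genotype had 2 libraries. Total counts were 19047148 and 19396809 in WT replicates 1 and 2, and 19306140 and 19804951 in Tex11PM/Y libraries A and B. At this depth 3 counts, the limit that a count of 0 allows, correspond to between 0.149 and 0.169 CPM (counts scaled to library size) in a library. The labels do not say whether libraries of a genotype came from separate cultures or animals. The p-values therefore measure the spread between these samples only, which need not be that between animals. Genes of the fibroblast list took 2.27% and 0.739% of counts in WT replicates 1 and 2, and 0.0742% and 0.858% in libraries A and B. These shares argue against repeats of the same RNA sample.

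Tex11 transcripts were lower in both Tex11PM/Y libraries than in either WT library. WT replicates 1 and 2 held 66.4 and 126 CPM, from 1182 and 2491 counts, and Tex11PM/Y libraries A and B held 22.7 and 9.32 CPM, from 450 and 187 counts. Group means were 96.2 ± 42.1 CPM in WT and 15.99 ± 9.44 CPM in Tex11PM/Y (SD, n = 2 each). The gene, ENSMUSG00000009670.11, lies on the minus strand of chromosome X from 100838648 to 101059667 in mm10. Its log2 fold change was -2.59 with a standard error of 0.54, and did not pass the threshold over all genes (edgeR adjusted p = 0.884). The log2 fold change was -2.13 without Tex11PM/Y library B and -3.36 without library A, fits that each leave 1 Tex11PM/Y library. With DESeq2 Tex11 missed the threshold (log2 fold change -2.62, DESeq2 adjusted p = 0.0637). It passed with no filter on low counts (edgeR adjusted p = 1.28e-05). The labels describe no sequence change, so the level of the transcript does not test one.

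**Figure D1:**
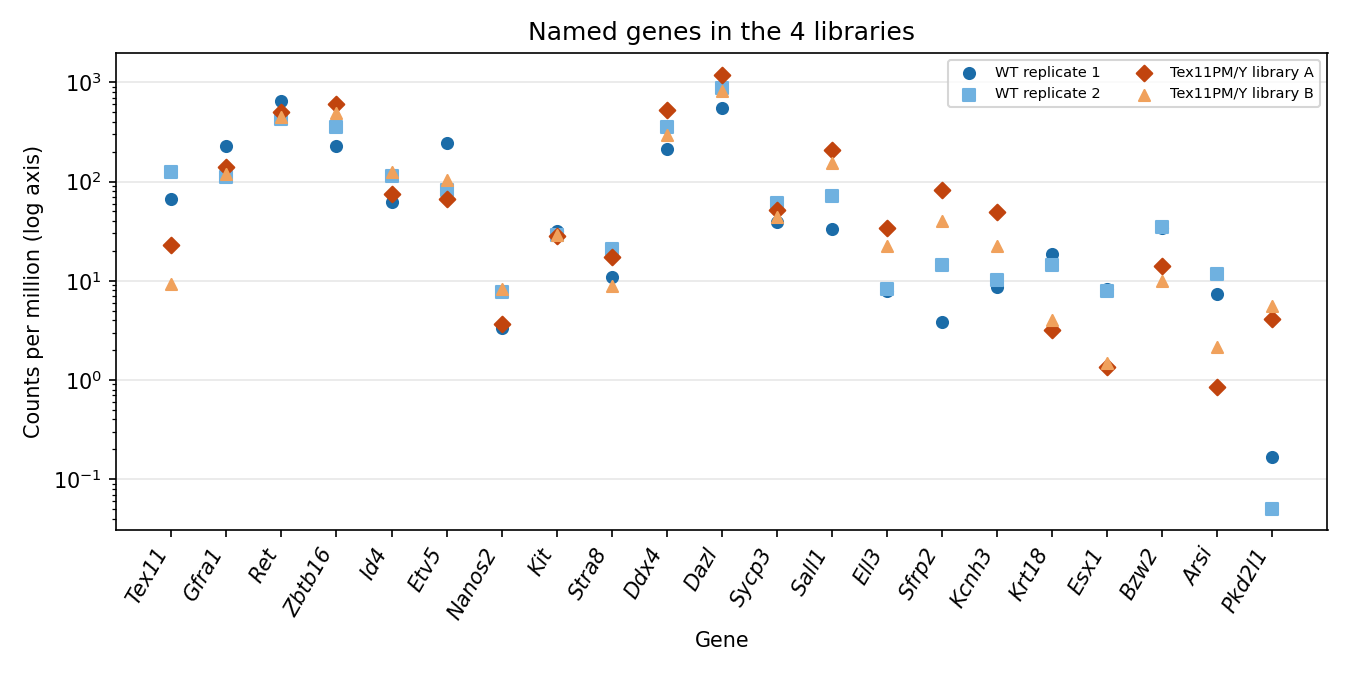
CPM (log axis) of genes named in the text in each of the 4 libraries, 1 point per library. Tex11 lies between 9.32 and 22.7 in the Tex11PM/Y libraries and between 66.4 and 126 in WT, while Kit lies between 28.6 and 31.9 in all 4.

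Outside Tex11, genes with the smallest p on the higher side included Sall1, Ell3, Sfrp2 and Kcnh3, and none of them passed the threshold over all genes. Sall1, a zinc-finger transcription factor, had 52.2 ± 27.4 CPM in WT and 181 ± 38.2 CPM in Tex11PM/Y (SD, n = 2 each; log2 fold change 1.79, standard error 0.43). Sfrp2, a secreted Wnt modulator, had 9.04 ± 7.38 and 60.9 ± 29.9 CPM. The elongation factor gene Ell3 had 8.08 ± 0.30 and 28.01 ± 7.97 CPM, and the potassium channel gene Kcnh3 had 9.44 ± 1.03 and 36.1 ± 19.19 CPM. On the lower side stood Tex11, Krt18, Esx1, Bzw2 and Arsi. Krt18, a keratin of simple epithelia, had 16.5 ± 3.15 CPM in WT and 3.60 ± 0.54 CPM in Tex11PM/Y, and Esx1, an X-linked homeobox gene, had 8.08 ± 0.34 and 1.43 ± 0.10 CPM. Bzw2 had 34.4 ± 0.34 and 12.1 ± 2.92 CPM, and the sulfatase gene Arsi had 9.47 ± 3.06 and 1.499 ± 0.91 CPM. Each of these genes had an edgeR adjusted p of 0.884. Without library B, which left 1 Tex11PM/Y library, log2 fold changes were 1.95 for Sall1, 3.135 for Sfrp2 and 2.35 for Kcnh3. With no filter on low counts Sall1 (edgeR adjusted p = 0.00334) and Sfrp2 (edgeR adjusted p = 0.000143) passed. Without WT replicate 2 the log2 fold change of Sfrp2 went from 2.75 to 3.96. That of Kcnh3 went from 1.94 to 1.26 without library A, and to 1.09 with the fibroblast list as covariate. Sall1 lies on chromosome 8, raised in WT replicate 1, but held 32.9 CPM there and 71.6 CPM in WT replicate 2. Bzw2 lies on chromosome 12, raised in WT replicate 2, but held 34.2 and 34.6 CPM in WT replicates 1 and 2.

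Of 17262 genes tested with edgeR, 0 were higher and 0 lower in Tex11PM/Y at an adjusted p under 0.05, with or without a minimum log2 fold change of 1. An unadjusted p under 0.05 was reached by 171 genes with higher and 295 with lower counts, 466 in all, against 863.1 expected by chance. DESeq2 called 1 gene higher and 0 lower, and limma on FPKM or TPM called 0. The gene called by DESeq2 was the ion channel gene Pkd2l1, chosen after its values were seen, with 3 and 1 counts in the WT libraries and 82 and 111 in the Tex11PM/Y libraries (DESeq2 adjusted p = 0.00229; edgeR adjusted p = 0.884). The biological coefficient of variation was 43.4%, and the groups did not overlap at 32.4% of genes, where chance gives 33.3%. Without Tex11PM/Y library B edgeR called 74 genes higher and 444 lower. Without any count filter it called 16 higher and 34 lower.

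The genotypes did not separate in the transcriptome as a whole. WT replicate 2 and Tex11PM/Y library B were the closest pair, with a Pearson r across genes of 0.984 and 980 genes that differed by over 2-fold, whereas the WT replicates reached 0.950 with 3813 such genes and the Tex11PM/Y libraries 0.925 with 4260. Genes are not independent replicates, so these r values only describe the libraries. The first principal component held 67.8% of the variance, with WT replicate 1 at -82.2 and Tex11PM/Y library A at 107 on its ends.

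Markers of undifferentiated spermatogonia had no common direction between the genotypes. Zbtb16, a transcription factor needed for SSC self-renewal, had 227 and 355 CPM in WT and 608 and 489 CPM in Tex11PM/Y (log2 fold change 0.91, standard error 0.34, edgeR adjusted p = 0.884). Gfra1 and Ret, which together form the GDNF receptor, had log2 fold changes of -0.39 (standard error 0.39) and -0.19 (standard error 0.33). Id4 had 0.18 (standard error 0.41), Nanos2 0.12 (standard error 0.71) and Etv5 -0.95 (standard error 0.53). The differentiation genes Kit and Stra8 had -0.09 (standard error 0.36) and -0.27 (standard error 0.56). The germ cell genes Ddx4 and Dazl had 0.54 (standard error 0.40) and 0.49 (standard error 0.37), and Sycp3, of the synaptonemal complex, had -0.05 (standard error 0.36). None of these 11 markers passed the threshold. Without WT replicate 1 the values of Gfra1, Ret and Etv5 turned to 0.19, 0.13 and 0.04, and those of Id4 and Nanos2 to -0.19 and -0.37. With a library left out Ddx4 ranged from 0.062 to 0.93 and Dazl from 0.17 to 0.84.

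In the germline lists, genes of the piRNA pathway and germline DNA methylation were higher in Tex11PM/Y with the preset correlation, and SSC, differentiation and meiotic genes did not pass the test. The piRNA list had a mean log2 fold change of 0.37, with 21 of 26 tested members fitted higher (camera adjusted p = 0.0199; adjusted p = 0.629 with an estimated correlation). Its members included Tex19.2 (9.39 ± 5.02 CPM in WT and 25.2 ± 5.97 in Tex11PM/Y), Tdrd5 (188 ± 68.0 and 285 ± 34.4) and Piwil4 (24.4 ± 18.0 and 44.1 ± 1.48). The Y-linked list was called higher too, with a mean of 0.76 and 7 of 8 members fitted higher (camera adjusted p = 0.0199; adjusted p = 0.604 with an estimated correlation); Usp9y held 15.2, 22.3, 88.0 and 18.7 CPM in WT replicates 1 and 2 and libraries A and B. In that order the list averaged 3.91, 4.19, 5.53 and 4.11 log2 CPM, the reverse ranking of the fibroblast list below, and its mean log2 fold change was 0.057 without library A and -0.15 with the fibroblast list as covariate. The call of the piRNA list ended without WT replicate 1 (mean 0.088, adjusted p = 0.380) or library B (mean 0.23, adjusted p = 0.480), while without WT replicate 2 its mean was 0.61. The call of the Y-linked list ended without WT replicate 2 (adjusted p = 0.113) or library A (adjusted p = 0.801). Mean log2 fold changes were 0.02 for 40 genes of SSC and undifferentiated spermatogonia (adjusted p = 0.623), -0.37 for 19 genes of differentiating spermatogonia (0.0815) and 0.11 for 44 meiotic prophase genes (0.323). They were 0.24 for 13 crossover factors other than Tex11 (adjusted p = 0.218), 0.22 for 16 spermatid genes (0.218), 0.32 for 20 X-linked germ cell genes other than Tex11 (0.0502) and -0.17 for 18 pluripotency genes (0.435). The pluripotency list passed without WT replicate 1 (mean -0.53, adjusted p = 0.00374).

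In each of the 32 lists 0 members passed the edgeR threshold over all genes tested, and 0 passed when adjusted over the list alone. With the preset correlation 3 lists were higher and 13 lower. With an estimated correlation 0 were called, the smallest camera adjusted p being 0.604. Fry called 0, the smallest fry adjusted p being 0.0772, for the list of differentiating spermatogonia. The mean of that list stayed lower with each library left out, from -0.48 to -0.30 log2. The sign of the mean, the median and the test was the same in every list.

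The lists of ribosomal proteins, glycolysis, oxidative phosphorylation and histones were lower in Tex11PM/Y with the preset correlation, and none was with an estimated correlation. The ribosomal protein, histone and mitochondrially encoded lists, and the heat shock list, were drawn up as signs of RNA quality. Of 73 ribosomal protein genes 72 were fitted lower, with a mean log2 fold change of -0.71 (camera adjusted p = 4.85e-15); Rps29 had 237 ± 19.01 CPM in WT and 121 ± 8.24 CPM in Tex11PM/Y. The glycolysis and hypoxia list had 25 of 26 members fitted lower, with a mean of -0.98 (camera adjusted p = 1.23e-06); Aldoa held 868, 863, 200 and 607 CPM in WT replicates 1 and 2 and libraries A and B. Nuclear-encoded oxidative phosphorylation had a mean of -0.25 over 40 genes (adjusted p = 0.0199) and replication-dependent histones -0.66 over 19 genes (adjusted p = 0.000251). With an estimated correlation the adjusted p was 0.604 for the ribosomal, glycolysis and histone lists and 0.650 for oxidative phosphorylation. Like the fibroblast list, each of these lists was lowest in library A. From WT replicate 1 to 2, where fibroblast genes fell, ribosomal protein and oxidative phosphorylation genes fell too (by 0.74 and 0.24 log2), and glycolysis and histone genes rose (by 0.08 and 0.10). The glycolysis call ended without library A (mean -0.24, adjusted p = 0.151), and oxidative phosphorylation without library A (mean 0.0044, adjusted p = 0.851) or WT replicate 1 (adjusted p = 0.285). Across left-out libraries the means ranged from -1.71 to -0.24 for glycolysis, from -1.10 to -0.36 for ribosomal proteins and from -1.05 to -0.32 for histones. Mitochondrially encoded genes had a mean of 0.22 over 14 genes (adjusted p = 0.223), and passed without WT replicate 1 (mean 0.53, adjusted p = 0.00575) or library B (mean 0.64, adjusted p = 0.0486). The 33 genes of the cell cycle had a mean of 0.23 (adjusted p = 0.108), and the 25 genes of cholesterol synthesis -0.08 (adjusted p = 0.549).

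Signalling and stress lists were mostly lower as well with the preset correlation. With an estimated correlation none was called, with an adjusted p of 0.629 for the recombination list and 0.604 for the other 6 lists called here. The GDNF, FGF and ERK response list had 26 of 30 members fitted lower, with a mean log2 fold change of -0.79 (camera adjusted p = 0.000305); the immediate-early gene Fos held 423, 227, 14.2 and 107 CPM in WT replicates 1 and 2 and libraries A and B. The heat shock and handling response list shares Fos, Junb, Egr1 and Ier2 with the ERK list, so the calls of the lists are not independent. The mean of the heat shock list was -1.13 over 20 genes (camera adjusted p = 0.000305). Its member Hspa1b had 105 ± 35.7 CPM in WT and 49.0 ± 9.98 CPM in Tex11PM/Y. The p53 targets had a mean of -0.47 over 27 genes (adjusted p = 0.0199), among them Btg2 at 238 ± 25.5 and 74.7 ± 56.1 CPM. The retinoic acid response list had -0.72 over 16 genes (adjusted p = 0.0199), BMP and TGF-beta targets -0.70 over 19 genes (0.0199) and interferon-stimulated genes -0.31 over 33 genes (0.0243). Genes of homologous recombination and the DNA damage response went the other way, with a mean of 0.30 and 28 of 35 fitted higher (adjusted p = 0.0199), among them Exo1 at 69.3 ± 17.6 and 110 ± 26.1 CPM. Like the fibroblast list, the lower lists had their lowest mean in library A; the recombination list had its highest there, at 6.07 log2 CPM, and its lowest in WT replicate 1, at 5.34. From WT replicate 1 to 2 the heat shock, p53, retinoic acid, ERK and BMP lists fell with the fibroblast list (by 0.75, 0.50, 0.35, 0.24 and 0.14 log2), and interferon genes rose by 0.21. Without library A the calls of the ERK (mean -0.21, adjusted p = 0.314), p53 (-0.28, 0.0937), BMP (-0.15, 0.682), interferon (-0.038, 0.682) and recombination (0.099, 0.504) lists ended. Without WT replicate 1 those of p53 (mean -0.24, adjusted p = 0.368), retinoic acid (-0.45, 0.164) and recombination (0.073, 0.516) ended. Without library B the means of the ERK, BMP and interferon lists were -1.41, -1.28 and -0.64. Without WT replicate 2 those of retinoic acid (adjusted p = 0.0923), BMP (0.167) and interferon (0.267) ended, and without library B that of retinoic acid (0.0619). Across left-out libraries the mean of the heat shock list ranged from -1.76 to -0.54. Imprinted genes had a mean of -0.20 over 37 genes (adjusted p = 0.217), and passed without library A (mean -0.40, adjusted p = 0.00459). The integrated stress and unfolded protein response list had -0.18 over 29 genes (adjusted p = 0.260), and Wnt targets 0.26 over 12 genes (adjusted p = 0.215).

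Fibroblast and macrophage markers differed more between libraries A and B than between the genotypes. The fibroblast list averaged 8.05 and 6.63 log2 CPM in WT replicates 1 and 2 and 3.10 and 6.65 in libraries A and B, and took 2.27%, 0.739%, 0.0742% and 0.858% of their counts. Col1a1, a fibrillar collagen, held 4710, 995, 102 and 1531 CPM in the same order. As a list, fibroblast genes had a mean log2 fold change of -2.46 with 29 of 29 fitted lower (camera adjusted p = 2.03e-12), and peritubular myoid genes -1.41 over 11 genes (adjusted p = 0.000251), with Acta2 and Tagln held by both lists. The adjusted p of both was 0.604 with an estimated correlation. Across left-out libraries the means ranged from -4.28 to -0.69 for fibroblasts, the smallest without library A, and from -2.03 to -0.83 for myoid cells. Macrophage and leukocyte genes had -1.44 over 14 genes (camera adjusted p = 0.0199; adjusted p = 0.650 with an estimated correlation), but turned to 0.69 without library A (adjusted p = 0.000158) and ended without WT replicate 2 (adjusted p = 0.120). Lyz2, a lysozyme of macrophages, held 530, 417, 13.1 and 1052 CPM in WT replicates 1 and 2 and libraries A and B. Sertoli cell genes had -0.58 over 11 genes (adjusted p = 0.0502), and passed without WT replicate 1 (adjusted p = 0.0305) or library A (adjusted p = 0.00761). Endothelial genes had -0.21 over 9 genes (adjusted p = 0.549) and Leydig cell genes -0.0041 over 4 genes (adjusted p = 0.851).

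**Figure D2:**
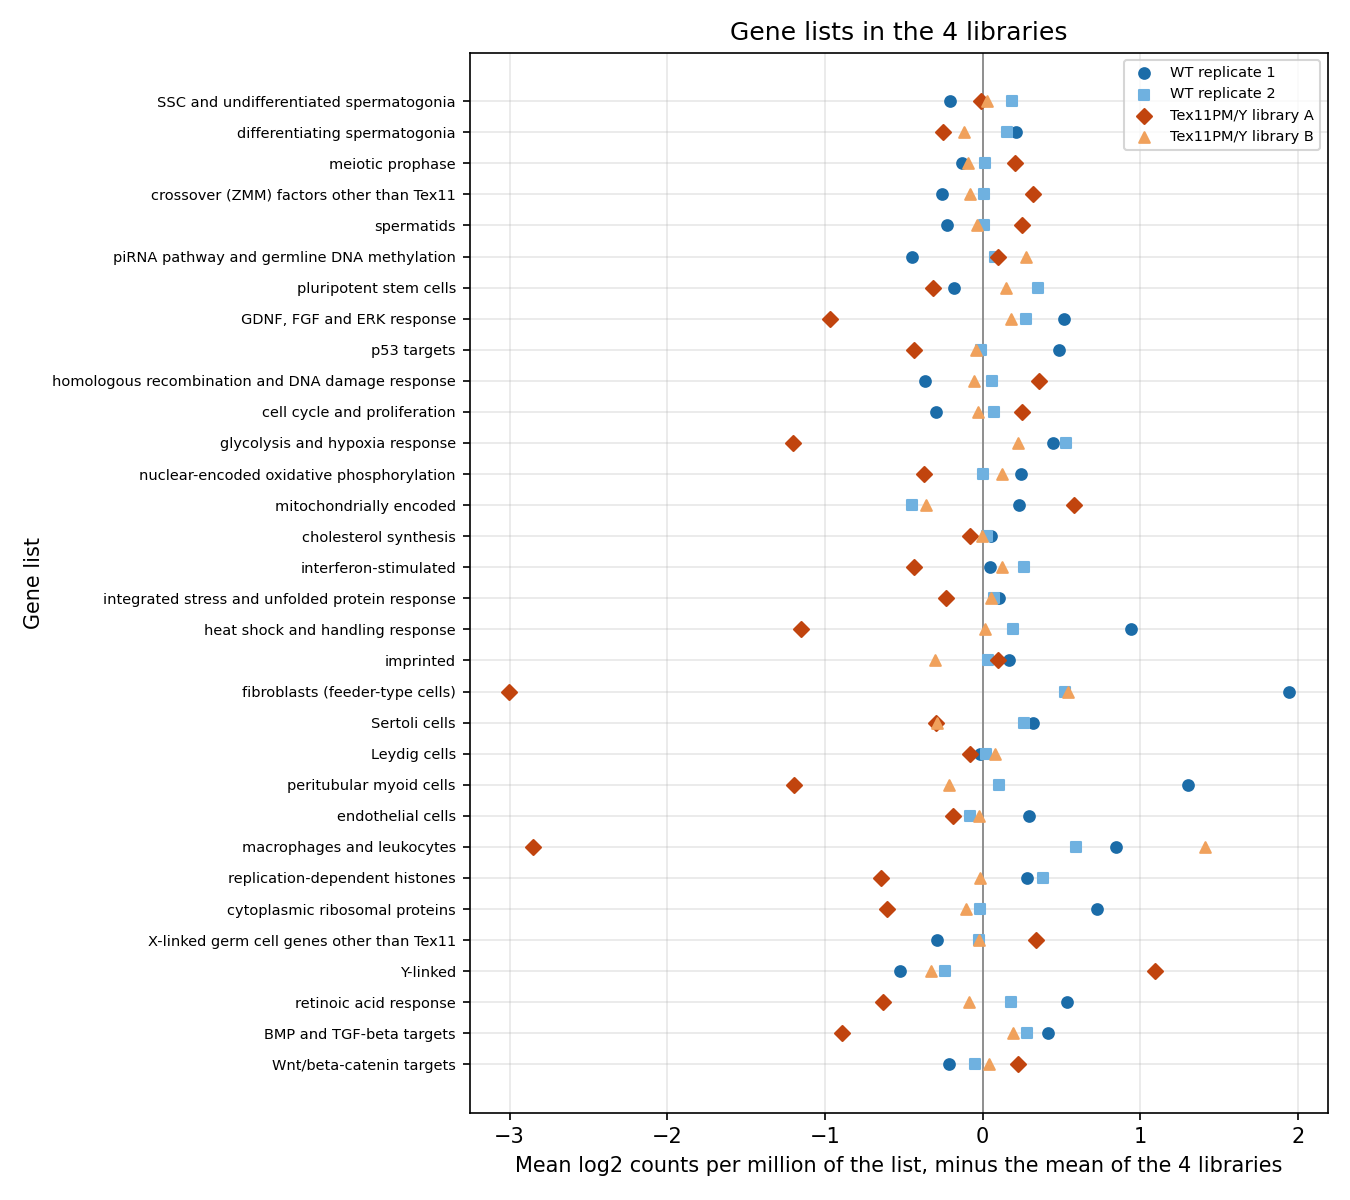
Mean log2 CPM of each of the 32 gene lists in each library, minus the mean of the 4 libraries, 1 point per library. The fibroblast list spans from 3.10 in Tex11PM/Y library A to 8.05 in WT replicate 1, before subtraction.

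By position, chromosomes 12 and 8 stood out, each through a WT library. Genes of chromosome 12 were higher in WT replicate 2 than in the mean of the other 3 libraries by a median of 0.57 log2 over 632 tested genes (bootstrap 95% interval from 0.55 to 0.61), with 90.7% of them above 0. Genes of chromosome 8 were higher in WT replicate 1 by a median of 0.40 over 921 genes (bootstrap 95% interval from 0.35 to 0.45). Among the other 18 (autosomes and X) the largest median was -0.21, on chromosome 13 in WT replicate 1. Between the genotypes the median log2 fold change was -0.28 on chromosome 12, -0.19 on chromosome 8 and 0.11 on chromosome X. With 0 genes past the threshold, the planned Fisher exact test per chromosome called 0 chromosomes. Among genes with an unadjusted p under 0.05, a threshold added after the data were seen, chromosome 12 held 2 higher and 34 lower (5.70% of its genes against 2.59% elsewhere, Fisher exact test adjusted p = 0.000559). That test treats genes as independent and follows the shift of WT replicate 2, so it does not show a genotype difference. Without library B, chromosome 17 was the 1 chromosome called among 518 genes.

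**Figure D3:**
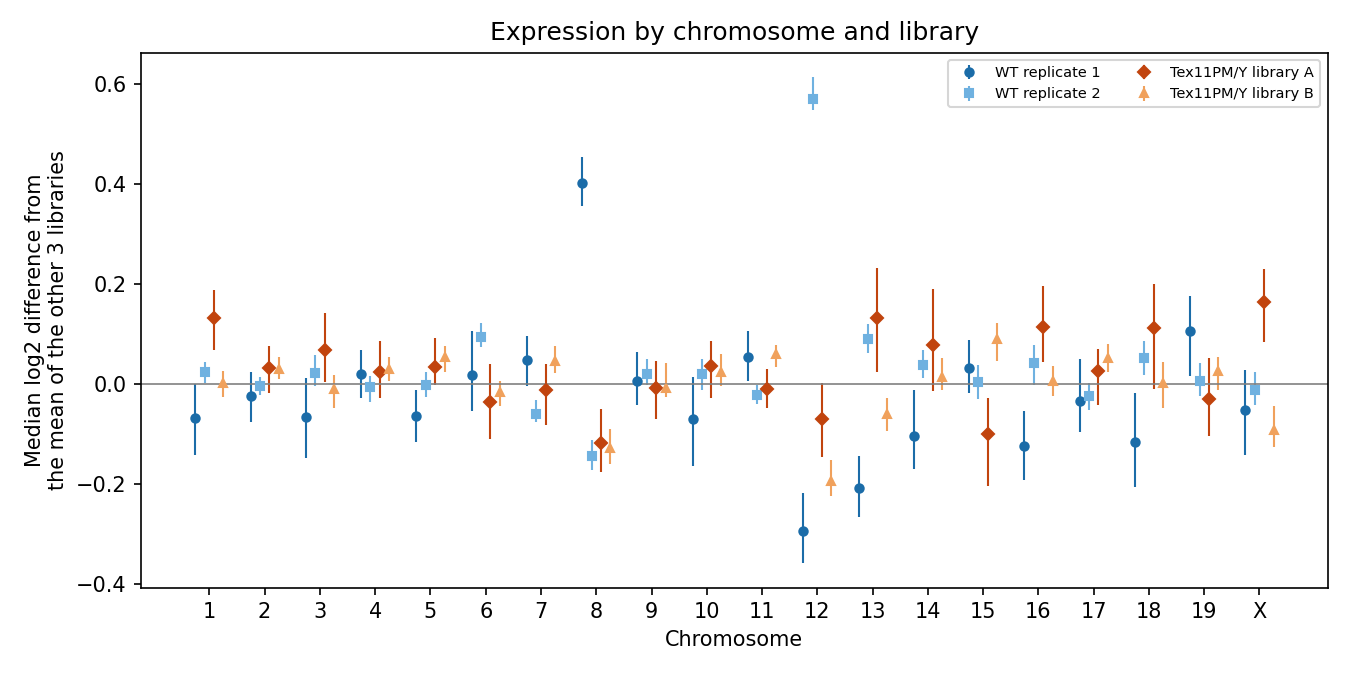
Median log2 difference of each library from the mean of the other 3, for the tested genes of each chromosome, with bootstrap 95% intervals as bars. Chromosome 12 stands at 0.57 in WT replicate 2 and chromosome 8 at 0.40 in WT replicate 1.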

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

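The fibroblast covariate and the unadjusted chromosome threshold were chosen after the results were seen. No paired analysis was possible because both Tex11PM/Y columns carry the same replicate number. Tex11 stayed lower in all 15 alternatives, from -3.66 to -2.08 log2 (adjusted p from 1.28e-05 to 1.0), and from -3.36 to -2.08 when a library was left out. Genes called higher numbered 1 with DESeq2, 16 without a count filter and 0 to 74 with a library left out; genes called lower numbered 34 without the filter and 0 to 444 with a library left out. Without the filter Tex11 had -2.63; the prior degrees of freedom became infinite there, against 5.22. Of the 50 genes then called, 48 are among the 17262, with the same direction in 48. Both fits use the same counts and contrast, so the shared direction adds no evidence for these calls. A lone library in a group is assumed to vary like the other group. List calls given for left-out libraries are those with the preset correlation. An estimated correlation and fry left 0 lists higher and 0 lower. Lower lists numbered 5 with the covariate and 8 to 12 with a library left out, and chromosomes called 1 at the unadjusted threshold and 0 to 1 with a library left out. TPM moved the median of all genes to 0.18. For the other changes the cause was not tested.

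Marker genes that turned did so without passing. With FPKM + 1, filtered or not, Kit had 0.0038 and Sycp3 0.061; with FPKM + 0.1 they had 0.0044 and 0.063; with TPM, Ret, Kit and Sycp3 had 0.051, 0.11 and 0.18. Library size alone gave 0.0050 for Sycp3 and 0.052 for Leydig genes. The covariate gave -0.16 for Ddx4 and -0.0064 for Dazl. Across left-out libraries Gfra1 ranged from -0.84 to 0.19, Ret from -0.48 to 0.13, Id4 from -0.26 to 0.65, Etv5 from -1.55 to 0.035, Nanos2 from -0.62 to 0.83, Stra8 from -0.83 to 0.26 and Sycp3 from -0.35 to 0.29. Of 313 comparisons of named genes other than Tex11, with Pkd2l1 among them, 280 kept direction and side, 10 passed and 23 turned.

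With the covariate, list means turned to -0.056 for SSC genes, -0.10 for meiotic prophase, -0.061 for crossover factors, -0.012 for spermatids, whose test stayed higher, -0.046 for recombination, -0.029 for the cell cycle, 0.11 for oxidative phosphorylation, -0.18 for mitochondrially encoded, 0.082 for Leydig, whose test stayed lower, and -0.15 for Y-linked genes. Macrophage genes turned to 1.17 and passed (adjusted p = 1.31e-07; all alternatives from 6.49e-13 to 0.706), but with an estimated correlation the covariate called 0 lists (adjusted p = 1.0). Of 15 called lists other than fibroblasts, 4 stayed called in their direction with the preset correlation. They were the piRNA and ribosomal protein lists (camera adjusted p = 0.00951 for both), the myoid list (0.0296) and the histone list (0.0414). The covariate leaves fewer residual degrees of freedom than the 2 of the main fit, so gained and lost calls are weak evidence. Calls that ended included glycolysis (mean -0.14), ERK response (-0.046) and heat shock (-0.25). Imprinted genes (mean -0.41, camera adjusted p = 0.00207) and Sertoli genes (-0.57, 0.0319) gained a call. The fibroblast list has no value under its own covariate. That list differed between the groups, so the covariate cannot fully separate fibroblast RNA from genotype. Across left-out libraries the means ranged from -0.20 to 0.19 for SSC genes, -0.036 to 0.22 for meiotic prophase, -0.039 to 0.32 for spermatids, -0.54 to 0.0044 for oxidative phosphorylation, -0.25 to 0.64 for mitochondrially encoded, -0.40 to 0.018 for imprinted, -0.13 to 0.077 for Leydig and -3.61 to 0.69 for macrophage genes. Without turning, they ranged from 0.045 to 0.40 for crossover factors, 0.023 to 0.39 for the cell cycle, 0.14 to 0.45 for X-linked germ cell, 0.029 to 0.33 for Wnt, -0.36 to -0.035 for integrated stress, -0.17 to -0.042 for cholesterol and -0.64 to -0.16 for endothelial genes. Sertoli and X-linked germ cell genes passed with library size alone (adjusted p = 0.0495 for both) and with the stricter filter (0.0300 and 0.0349). Of the list comparisons, 195 kept direction and side, 58 lost and 12 gained the call; 22 turned.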

Other observations

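In Tex11PM/Y library A some germ cell and cell cycle genes were far above the other libraries; the 3 named here were picked after their values were seen, and no test was made of them as a group. Tex15, a germ cell gene of piRNA-directed silencing, held 489 CPM there and 87.9, 115 and 70.4 CPM in WT replicates 1 and 2 and library B. Sycp2, of the synaptonemal complex, held 201 CPM against 24.0, 40.4 and 31.2, and the proliferation marker Mki67 350 CPM against 55.6, 112 and 68.5. In a count added after these values were seen, 22 of 44 meiotic prophase genes were highest in library A, 6 of them by over 2-fold above every other library, and 12 were lowest there. Of 33 cell cycle genes 12 were highest there, 3 by over 2-fold, and 5 lowest. The same counts over all tested genes are not given here, and library A lay at an end of the first principal component. These counts therefore do not show a trait of the 2 lists. By exon length, the longest of 3 equal classes of tested genes had a median of 0.18 log2 above the other libraries in library A, and the shortest -0.13. In WT replicate 1 these medians were -0.16 and 0.12.

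The imprinted list did not pass in the main fit: 18 of 37 members were fitted higher and 19 lower. Its mean was -0.41 with the fibroblast list as covariate, and turned to 0.018 without library B. Some lower members are named here after their values were seen. H19 had 437 ± 319 CPM in WT and 135 ± 20.4 CPM in Tex11PM/Y, Grb10 58.7 ± 31.3 and 17.9 ± 7.76, Meg3 34.5 ± 16.8 and 12.9 ± 7.70, and Dlk1 32.0 ± 12.99 and 13.4 ± 5.31 (SD, n = 2 each). Dlk1 and Meg3 lie in 1 imprinted domain on chromosome 12, which was raised by 0.57 log2 in WT replicate 2, though both were highest in WT replicate 1. None passed the threshold.

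The fibroblast tests on chromosomes and the germ cell test on Tex11 were chosen after the results were seen. Chromosome 12 in WT replicate 2 and chromosome 8 in WT replicate 1 were raised along their whole length. The lowest of 5 position bins had a median of 0.51 on chromosome 12 and 0.34 on chromosome 8. The amount of fibroblast RNA alone does not account for this. Library B and WT replicate 2, close in the fibroblast list, differed by -0.57 on chromosome 12, though this in part restates the pattern. Libraries A and B, far apart in that list, differed by -0.0023 on chromosome 8. Neither comparison tells which cells carried a shift. Transcript length does not account for the shifts either, as the lowest of 3 length classes kept 0.55 and 0.31. A candidate explanation is a gain of the chromosome in part or all of each WT culture: 3 copies in place of 2 in every cell would give 1.5-fold, and the ratios were 1.48 and 1.32. DNA was not analysed here, so this stays a hypothesis.

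The 16 lists called between genotypes may in part follow RNA from fibroblast-type cells, although the cells were collected on a sorter. Across 31 other lists, the difference of library A from B and that of WT replicate 2 from 1, each the fibroblast-poorer minus the richer, correlated with a Spearman rho of 0.46 (Pearson 0.31; permutation p = 0.0104 for rho). Over the 15 called lists alone, a test added after that result, rho was 0.41 and missed the threshold (permutation p = 0.133). Lists also share genes, so the evidence is limited. WT replicate 1 and library A lay at opposite ends of the first principal component. Any source of that axis could give a positive rho, so the correlation cannot single out fibroblast RNA. With the fibroblast list as covariate 4 of the 15 called lists stayed called in their direction, and macrophage genes turned to 1.17. With an estimated correlation 0 lists were called. The fibroblast list itself differed between the groups, so this fit cannot fully separate fibroblast RNA from genotype. Removing each library's trend on transcript length left 15 of 16 called, against length as the whole cause. The list lost was oxidative phosphorylation (camera adjusted p = 0.0735). In 15 of the 16 lists library B lay nearer to WT replicate 2 than to library A, and in 10 the groups did not overlap. An effect of the genotype stays open.

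The lower Tex11 level was set against a smaller share of germ cells and a lower signal of its region. A median of 0.040 log2 over 41 germ cell genes, with quartiles at -0.37 and 0.45, argues against a smaller share of undifferentiated spermatogonia. Nearly all of these genes come from the SSC list, whose values were known when the test was chosen. The test cannot decide on later germ cells, as it leaves out the differentiating spermatogonia list (mean -0.37, camera adjusted p = 0.0815). A median of 0.27 over 67 tested genes within 5 Mb of Tex11 argues against the second. An effect of the genotype may be the source, as a hypothesis from 2 libraries each.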
